A study of Prodigiosinella confusarubida with 6 samples.

How the data were processed

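RNA was sequenced from 6 cultures of the prodigiosin-producing bacterium Serratia sp. ATCC 39006, which is catalogued as Prodigiosinella confusarubida. Per the labels, 3 cultures received 15.6 µM ambigol C, a natural product of the cyanobacterium Fischerella ambigua, and 3 received the solvent DMSO alone. The labels differ on timing: the treatment label gives an incubation of 10 h, and the extraction protocol gives 7 h of growth in multiwell plates. Which of these was the harvest time was not resolved here. Per the labels' protocols, cells were placed in an RNA stabilising reagent, total RNA was column-purified and treated with DNase, rRNA was depleted with an enzymatic kit, and libraries were made with a NEBNext Ultra II RNA kit.

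The deposited files hold raw read counts per locus identifier, 1 file per culture, and are not normalised. Per the submitters' processing notes, HISAT2 2.1.0 and featureCounts 1.6.4 were used, along with FastQC and DESeq2 1.22.1. Per the file headers, the counts come from HISAT2 alignments. The genome build, the annotation version, the strand setting and the treatment of reads that match several places are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be assigned with certainty, and reads of near-identical copies may have been split or dropped. Each file lists the same 4444 identifiers.

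The identifiers are locus tags without gene names, products or coordinates, and no annotation was used here. The 33 gene lists fixed before the data were examined (prodigiosin synthesis, carbapenem, gas vesicles, motility, phosphate starvation, efflux, ribosomal proteins and others) were written by gene symbol and product. None of the 33 could be matched, so list tests, a count over the prodigiosin genes and the rRNA share were not made, nor were the alternatives planned for them. For the same reason, results are given per identifier, with only 2 identifiers printed per direction.

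Library totals ranged from 15223812 to 17077081 counts. Counts were tested with edgeR 4.0.16 under R 4.3.3. Identifiers were kept by filterByExpr, which left 4384 of 4444, and libraries were scaled by TMM. A negative binomial model with the treatment as its only term was fitted to all 6 libraries with glmQLFit and tested with glmQLFTest, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 4384 identifiers, with a threshold of 0.05. A second count required a change of at least 2-fold. Standard errors and 95% intervals of log2 fold changes were computed from the fitted weights and the posterior quasi-dispersion. Abundance is given as TMM-normalised CPM (counts scaled to a common library size), computed here from the deposited counts, as mean ± SD over the 3 cultures of a group. Intervals rest on a variance drawn mostly from all identifiers (39.2 prior against 4 residual degrees of freedom). They can be too narrow for an identifier whose own spread among the cultures is large.

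The naming rule was fixed before the data were examined. It took identifiers by size of change among those past the threshold whose 3 values in one group all lay above the 3 in the other and whose mean reached 10 CPM in the higher group. It planned 10 per direction. The first 2 that fell and the first that rose are printed. One further identifier that rose is printed because it was the only one past the threshold with a rise of at least 2-fold; it was chosen after its values were seen. Runs of next-numbered identifiers, meaning tags that differ by the usual step of 5, were also defined after the values were seen.

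The procedure was tested on simulated counts for the 4384 identifiers, with 200 identifiers changed. Counts were drawn independently per identifier with the libraries' means and totals and the fitted trend of dispersion with abundance. Outlying spread of single identifiers and correlated neighbours were not simulated, so the rates below hold for that simpler setting. For the comparison of ambigol C with DMSO, edgeR recovered 62.7% of 67 identifiers changed by 1.3-fold, 83.6% of 67 changed by 1.5-fold and 90.9% of 66 changed by 2-fold. Of its 165 calls, 7 were for unchanged identifiers.

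The alternatives were RLE size factors, library size alone, no filter on low counts, a mean of at least 10 CPM, the replicate number as a block, DESeq2 1.42.0, limma-voom (limma 3.58.1), and leaving out each culture in turn. A robust prior, thinning of all libraries to the smallest total and removal of the 10 most abundant identifiers were added after the data were examined. No pair of libraries agreed within sampling noise, since the chi-square statistic per degree of freedom was at least 7.02 for pairs of the same group. This argues against repeated sequencing of 1 library, but it cannot tell separate cultures from separate preparations of 1 culture. Each library was taken as a separate culture and counted as 1 replicate.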

Results

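The transcriptome of Serratia sp. ATCC 39006 was profiled by rRNA-depleted RNA sequencing in 3 cultures given 15.6 µM ambigol C and 3 cultures given DMSO. This Gram-negative bacterium makes the red tripyrrole pigment prodigiosin. Ambigol C is a chlorinated aromatic compound of cyanobacterial origin, and the study's title concerns its effect on prodigiosin production. The ambigol C libraries held 15223812, 15283458 and 15243032 counts for replicates 1, 2 and 3. The DMSO libraries held 16876562, 15284137 and 17077081 counts. Each library had counts for 4424 to 4436 of the 4444 identifiers. The median count per identifier lay between 826 and 948. The 10 most abundant identifiers took 11.0% to 11.3% of the counts in every library. The locus identifiers in the files are not paired with gene names, so no value is given for the prodigiosin genes.

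The libraries of both groups were close to one another. The Pearson correlation of log2 CPM across identifiers was 0.992 to 0.993 within groups and 0.989 to 0.993 between groups. The common biological coefficient of variation was 8.17%. The first principal component of log2 CPM held 29.5% of the variance, with the 3 ambigol C libraries on one side and the 3 DMSO libraries on the other. Along it, ambigol C replicate 1, at -10.8, lay farther from the DMSO libraries than ambigol C replicates 2 and 3, at -5.53 and -3.99. DMSO replicate 2, at 11.0, lay as far out on the other side, with DMSO replicates 1 and 3 at 3.37 and 5.94.

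The design asks which transcripts change when ambigol C is added. Of 4384 identifiers tested, 154 (3.51%) changed, of which 91 rose and 63 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). Most changes were small. The median rise was 1.25-fold and the median fall 1.17-fold. Changes of at least 1.5-fold were found for 22 identifiers, of which 7 rose and 15 fell. Changes of at least 2-fold were found for 8, of which 7 fell and 1 rose. The groups did not overlap for 147 of the 154 identifiers. These were picked by a test on the same libraries, so this adds no separate support. Over all tested identifiers, 19.6% did not overlap, where chance gives 10% for 3 against 3. The count depended on single cultures: it was 49 without ambigol C replicate 1, 80 without ambigol C replicate 2, 76 without DMSO replicate 2 and 102 without DMSO replicate 3. It rose to 231 without ambigol C replicate 3. The count of 8 was 5, all falls, without ambigol C replicate 1, and 5 with a robust prior. When libraries were scaled by their totals alone, the share of rises among the calls went from 59.1% to 75.7%.

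**Figure D1:**
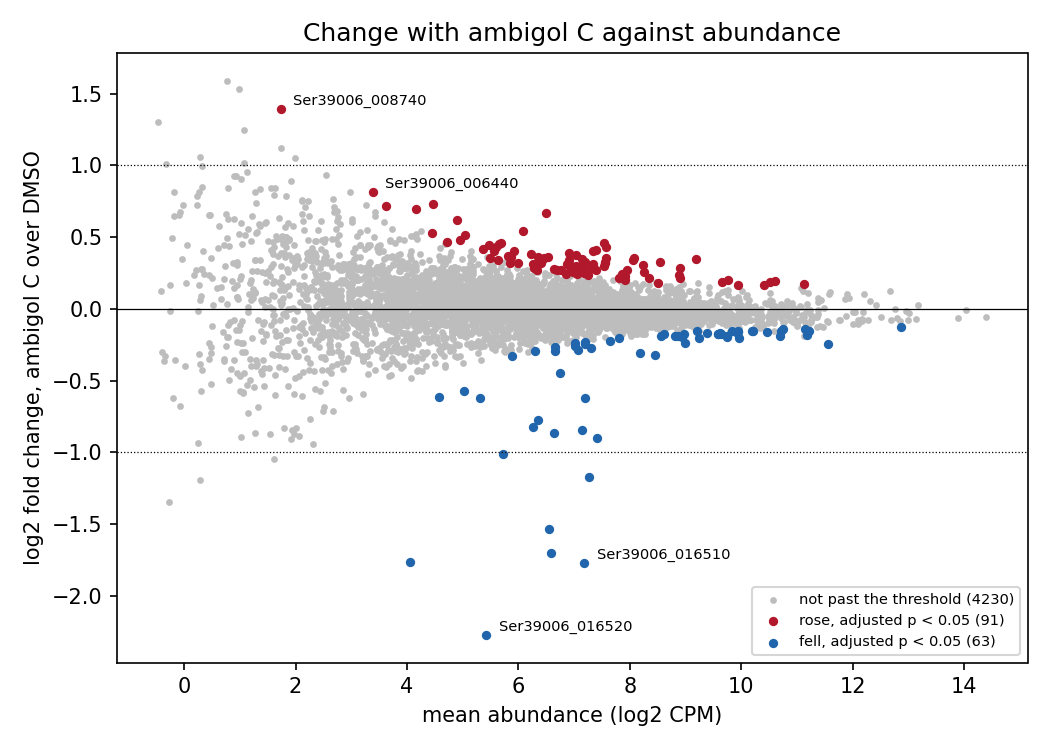
Log2 fold change of ambigol C over DMSO (vertical axis) against mean abundance in log2 CPM (horizontal axis) for the 4384 tested identifiers, 1 point each. The 91 that rose and the 63 that fell are coloured, dotted lines mark 2-fold changes, and the 4 named identifiers are labelled; the most negative values belong to a small set led by Ser39006_016520.

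The strongest change was a fall. Ser39006_016520 went from 70.8 ± 13.7 CPM in DMSO to 14.6 ± 2.75 CPM with ambigol C (SD, n = 3 per group), which is 4.83-fold lower. Its log2 fold change was -2.27 with a standard error of 0.13 (edgeR, adjusted p = 2.28e-17). Its groups did not overlap, which the naming rule required. Ser39006_016510 went from 223.8 ± 25.3 CPM to 65.6 ± 22.6 CPM, a 3.41-fold fall. Its log2 fold change was -1.77 with a standard error of 0.12 (edgeR, adjusted p = 1.64e-15). Here too the rule required groups that did not overlap. The call for Ser39006_016510 was lost with a robust prior, where its adjusted p in edgeR was 0.0622.

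Both belong to a run of 6 next-numbered identifiers that all fell, with log2 fold changes from -2.27 to -1.17. Summed over the 6, abundance was 819.6 ± 83.6 CPM in DMSO and 275.6 ± 80.1 CPM with ambigol C (SD, n = 3 per group), or 2.97-fold lower. Within the treated group the sum was 184.4 CPM in replicate 1, 307.8 CPM in replicate 2 and 334.7 CPM in replicate 3, against a lowest DMSO value of 759.1 CPM. All 6 members passed the threshold in edgeR with any single culture left out, and 3 of the 6 passed with a robust prior. A second run of 6 next-numbered identifiers, elsewhere in the numbering, fell by 0.62 to 1.01 on the log2 scale. Its sum went from 881.6 ± 111.8 CPM to 500.0 ± 30.2 CPM, or 1.76-fold lower. All 6 of its members passed the threshold under each alternative run. These 12 identifiers included each of the 7 past the threshold that fell at least 2-fold.

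**Figure D2:**
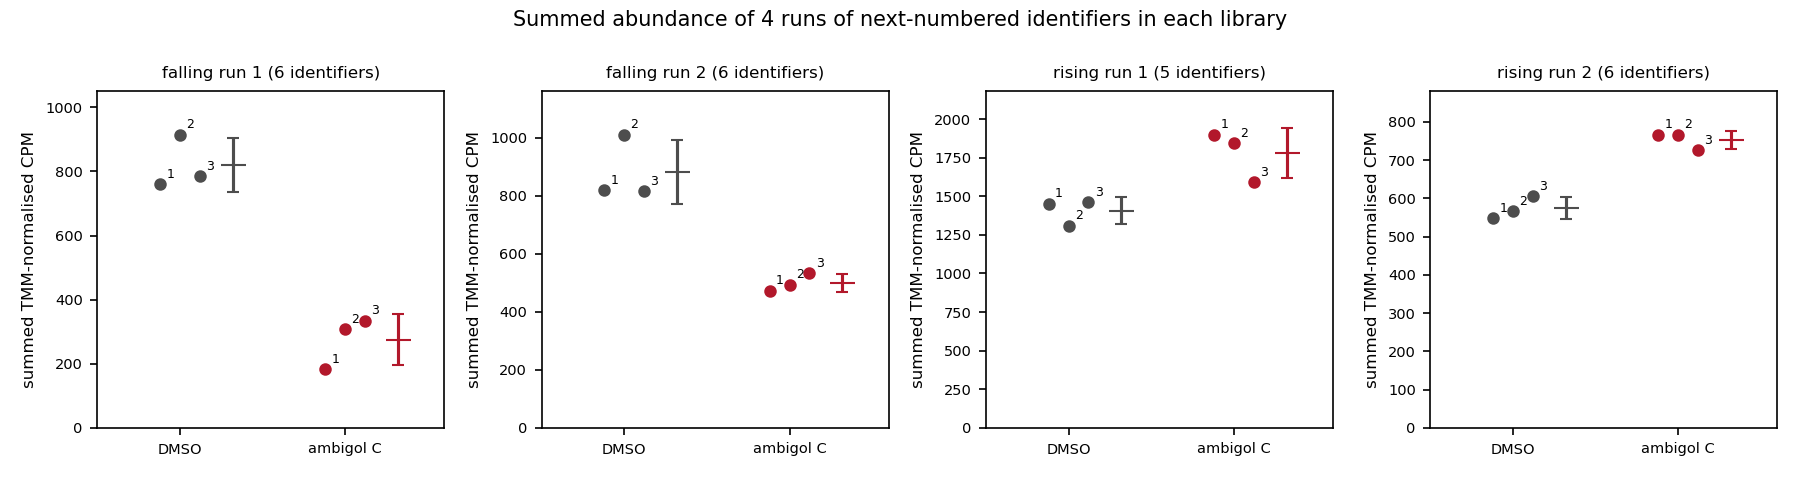
Summed TMM-normalised CPM (vertical axes, from 0) of 4 runs of next-numbered identifiers in each library; numbered points are cultures, and the bar beside them is the group mean with its SD (n = 3). The first falling run lies between 184.4 and 334.7 CPM with ambigol C and at 759.1 CPM or above in DMSO. That no run has overlapping groups was made likely by building runs from identifiers past the threshold.

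Few of the largest changes were rises, and the largest rises were in identifiers of low abundance. Ser39006_006440 went from 7.55 ± 2.39 CPM in DMSO to 13.3 ± 0.973 CPM with ambigol C (SD, n = 3 per group), or 1.76-fold higher. Its log2 fold change was 0.82 with a standard error of 0.22 (edgeR, adjusted p = 0.0296). Its groups did not overlap, as the naming rule required. With single cultures left out, its adjusted p in edgeR was 0.129 without ambigol C replicate 1, 0.0532 without ambigol C replicate 3, 0.0682 without DMSO replicate 2 and 0.192 without DMSO replicate 3. Ser39006_008740, the only identifier past the threshold with a rise of at least 2-fold, had 59 to 86 counts in the ambigol C libraries and 17 to 41 in the DMSO libraries. It went from 1.78 ± 0.695 CPM to 4.68 ± 0.888 CPM, or 2.63-fold higher. Its log2 fold change was 1.39 with a standard error of 0.38 (edgeR, adjusted p = 0.0277), and its groups did not overlap. Its adjusted p in edgeR was 0.107 without ambigol C replicate 1, 0.0909 without ambigol C replicate 3, 0.172 without DMSO replicate 1 and 0.0902 without DMSO replicate 2.

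Rises also came in runs. One run of 6 next-numbered identifiers rose by 0.27 to 0.67 on the log2 scale, and its sum went from 574.0 ± 29.2 CPM in DMSO to 753.1 ± 23.3 CPM with ambigol C (SD, n = 3 per group), or 1.31-fold higher. A run of 5 rose by 0.29 to 0.46, and its sum went from 1408 ± 84.6 CPM to 1780 ± 164 CPM, or 1.26-fold higher. No run had overlapping groups, but runs were built from identifiers already past the threshold in these libraries, so this adds no support. With a single culture left out, 4 to 6 of the 6 members passed the threshold in edgeR, the lowest value being without DMSO replicate 1. For the run of 5 it was 3 to 5 members, the lowest value being without DMSO replicate 2.

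**Figure D3:**
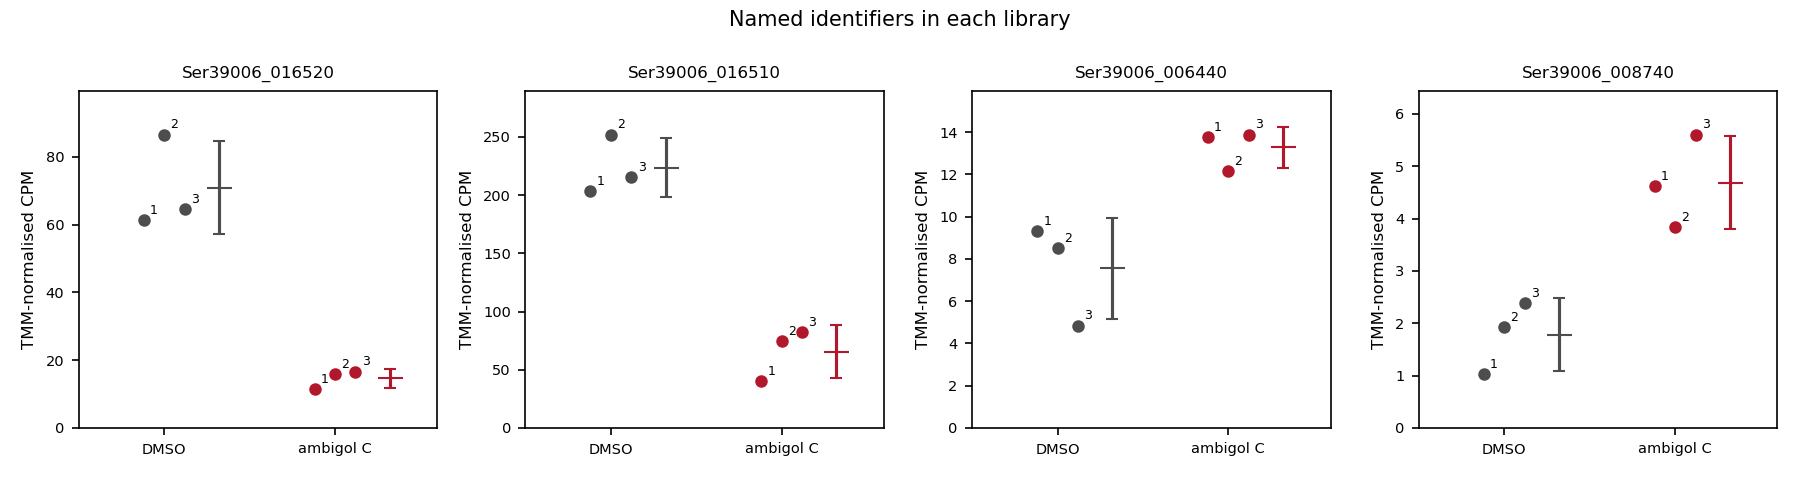
TMM-normalised CPM (vertical axes, from 0) of the 4 named identifiers in each library; numbered points are cultures, and the bar beside them is the group mean with its SD (n = 3). The 2 identifiers that fell are at 14.6 and 65.6 CPM on average with ambigol C against 70.8 and 223.8 CPM in DMSO, and the 2 that rose average 13.3 and 4.68 CPM with ambigol C.

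Relative to the TMM scaling, the depth allowed large changes to be ruled out for most identifiers. A shift shared by most transcripts would not be seen, and the intervals are not adjusted for the number of identifiers. The 95% interval of the fold change lay within 2-fold in both directions for 4071 identifiers (92.9%) and within 1.5-fold for 3509 (80.0%). For 5 identifiers, all in the first falling run, the interval lay wholly beyond 2-fold. Their intervals come from the main fit and were not recomputed with a robust prior, under which 3 of the 6 members of that run passed the threshold. The interval of the other 308 identifiers crossed 2-fold, and their median abundance was 2.64 CPM, against 66.6 CPM for those within 2-fold. Calls followed abundance in the same way. Of the 154, 98 lay in the most abundant tertile of identifiers (above 116.5 CPM), 48 in the middle tertile and 8 in the least abundant tertile (up to 25.9 CPM). For the 308 identifiers whose interval crossed 2-fold, a change of that size was neither shown nor excluded.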

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

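The robust prior, the thinning and the removal of abundant identifiers were chosen after the data were examined. The count of 154 changed identifiers stayed within 1.5 times under the alternative scalings, filters and tools, from 153 with thinning to 210 with DESeq2, and 151 of the 154 were also called by DESeq2. Leaving out 1 culture moved it most: it ranged from 49 (27 up and 22 down, without ambigol C replicate 1) to 231 (without ambigol C replicate 3). All 49 were among the 154. Fewer cultures were fitted in these cases. Why single cultures moved the count so far was not tested beyond the contrasts between cultures under other observations, which did not settle it. The count of 8 identifiers changed at least 2-fold ranged from 5 (without ambigol C replicate 1) to 10 (without ambigol C replicate 3), and was 5 with a robust prior, which gives identifiers with outlying spread a larger variance. Scaling by library totals alone gave 185 calls, with 140 up and 45 down, and moved the median log2 fold change of all identifiers from 0.00 to 0.03. The replicate numbers do not pair the cultures: same-numbered libraries had correlations of their deviations from -0.01 to 0.01, and 1 of 6 libraries correlated best with its own number. With the replicate block, 160 identifiers were called, of which 141 were among the 154. Of the named identifiers, Ser39006_016520 kept its call in all 16 alternatives, Ser39006_016510 in 15 of 16, Ser39006_006440 in 12 of 16 and Ser39006_008740 in 10 of the 14 that gave it an adjusted p. None reversed. Depth limits mainly the 308 identifiers whose interval crossed 2-fold, with a median of 2.64 CPM. The list tests, the prodigiosin count, the rRNA share and the removal of rRNA and tRNA genes were not run, since identifiers could not be matched to genes.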

Other observations

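The test on ambigol C replicate 1 in the first falling run was chosen after the results were seen. So were the runs and the comparison of neighbour correlations across splits. Predictions for the contrasts between cultures covered only ambigol C replicate 1 and DMSO replicate 2, and did not name Spearman's rho. In all, 47 of the 154 changed identifiers lay in 15 runs of at least 2, of which 24 identifiers rose and 23 fell.

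Next-numbered identifiers moved together. There were 32 neighbouring pairs called in the same direction, against a mean of 2.74 and a highest value of 9 over 1000 random orders (permutation p = 0.001, one-sided, the smallest they can give). The random orders ignored abundance, and calls lay mostly among abundant identifiers. If neighbours are alike in abundance, the random orders understate the pairs expected. The log2 fold changes of next-numbered identifiers correlated at 0.197 across identifiers, which are not independent replicates. The other 9 splits of the 6 libraries, each of which still holds part of the treatment difference, gave -0.0039 to 0.0914, so variation between cultures whatever the treatment did not reach the value of the real split. Without the called identifiers the correlation was 0.0939, above the highest of 1000 random orders, 0.0560. Over the same uncalled identifiers the other 9 splits gave -0.0049 to 0.0604, but 10 splits are too few for a share under 0.05. If the tags are numbered along the chromosome, as is usual in bacterial annotation, a candidate explanation for the runs is transcription as operons; reads shared between overlapping genes were not tested, since no coordinates were used.

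In the first falling run, ambigol C replicate 1 was the lowest culture. Without it the median log2 fold change of the 6 identifiers was -1.51, compared with -1.73 with it, so that culture does not make up the fall. The direct effect of the compound and an indirect one, through growth stage for example, stay open and untested for this run.

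For the count of 154, the real split of the libraries was the only 1 of 10 to reach it, and the highest of the other splits called 0; 10 splits are too few for a share under 0.05. Thinning to equal library totals gave 153 calls. The totals ranged only from 15223812 to 17077081, and the scaling already allows for them, so a much lower count was unlikely. Thinning therefore says little about the deeper DMSO replicates 1 and 3 as the source. It shows only that equal totals left the count nearly unchanged. Removing the 10 most abundant identifiers also gave 153, but it left the scaling as it was and so decides nothing about a few abundant identifiers. The difference between ambigol C replicate 1 and either other treated culture correlated with the change of the remaining treated culture against DMSO, at 0.0714 and 0.108 across identifiers, both above the highest of 1000 random orders (0.0502). Spearman's rho for these was 0.088 and 0.193, with highest random orders of 0.0618 and 0.0477. Both pairings above random orders had been set as the sign that replicate 1 carried a stronger form of the same change. They cannot settle it, since contrasts among the 3 treated cultures are tied by arithmetic. Some treated culture comes out positive in both pairings whatever the cause, though not always above random orders. Identifiers are also not independent replicates: next-numbered identifiers moved together, so the highest random orders can be too low. The hypothesis concerns 1 culture and stays open. The difference between ambigol C replicates 2 and 3 correlated with the change of replicate 1 at 0.0367, below its highest random order of 0.0488. Spearman's rho for it was 0.104, above its highest random order of 0.0534, so by rho the pattern was not particular to replicate 1. A bias in GC content or length could not be checked without gene models. The like test for DMSO replicate 2 gave 0.0024 and 0.0566, of which only the second exceeded its random orders. DMSO replicate 3 minus DMSO replicate 1 gave 0.0537, just above its highest random order of 0.0514. Both contrasts above random orders involve DMSO replicate 1, but they are tied in the same way and are not separate results. Spearman's rho was 0.0008 and 0.0417 for DMSO replicate 2 and 0.0341 for DMSO replicate 3 minus DMSO replicate 1, each below its highest random order (0.0464, 0.0489 and 0.0443). The measures differ, so whether untreated cultures vary along the same axis stays open.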
